A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

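Genomic DNA was prepared from asynchronous cultures of a WT and a pol32 strain, 2 libraries each. Per the labels, cells grew at 30 °C in medium with 2% raffinose to an optical density of 0.3 and were moved to 37 °C after galactose was added to 2% and doxycycline to 40 µg/ml. DNA was denatured and bound to an anion exchange resin at pH 12, and the fractions eluted at 800 to 900 mM salt were kept. Adaptors with random overhangs were ligated, and products of 200 to 800 bp were isolated on 2.5% agarose gels after PCR. Gel selection and PCR both favour some lengths, so the length distributions describe the libraries and not the cell.

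Each deposited file lists 1 row per distinct fragment with its chromosome number, first and last position, length, strand and the count of reads that gave it, per the labels. Counts were whole numbers in every row and the length was the last minus the first position plus 1 in every row, as checked on the files. The aligner, filters and genome build are not given in the sources used here. Chromosomes carry numbers from 1 to 18, and 17 and 18 were taken for mitochondrial DNA and the 2-micron plasmid from their highest positions (85778 and 6317) alone. The only gene table at hand was that of assembly R64, whose coordinates cannot be used with these files, so only the name, chromosome number and length of POL32 were taken from it. Densities of annotated genes, the gene lists, annotated origins, motif sites, tRNA genes, start codons, ribosomal DNA and Ty elements were therefore not analysed here. Windows of 5 kb took the place of genes, and origins were called from the strand switch. No columns of other samples were present.

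Reads were assigned by fragment midpoint to 5 kb windows of the 16 nuclear chromosomes. Windows were tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, adjusted p under 0.05 by Benjamini-Hochberg) in R 4.3.3. Chromosome densities, in log2 reads per kb per 1000000 reads with TMM scaling, were tested with limma 3.58.1. For fork direction, limma was run on log2 of Watson plus 0.5 over Crick plus 0.5 in windows with at least 100 reads in every library. Origins were called at steps of 100 nt as the local maxima, over 10 kb on each side, of the mean over the 4 libraries of the Watson share in the 10 kb to the left minus that to the right, with at least 1000 reads per flank and a value of at least 0.2. Calling origins on the mean of all libraries favours neither group, but positions where the value is high by chance are kept more often. Origin efficiencies were tested with limma. Lists of windows were tested with camera (preset correlation 0.01, and an estimated correlation beside it).

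Single values per library were compared by a two-sided exact permutation test over all 6 arrangements. Lengths were smoothed over 11 nt. The first peak was the maximum of the smoothed distribution, and the second was the highest local maximum (within 30 nt on each side) from 250 to 400 nt of the smoothed distribution over its mean across 151 nt, a rule set after the data were seen. Lost windows of 250 nt had over 5 reads per 1000000 in both libraries of 1 group and under 10% of the lower of these in both of the other, and the edges were refined in steps of 50 nt. End profiles were smoothed over 11 nt and divided by their mean across 1001 nt. Numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

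Depth was 92755003 and 55096375 reads in WT and 48289128 and 38470740 in pol32. Each share of reads carries a 95% Wilson interval that covers the counting error of reads only and takes PCR copies as independent. Replicates were compared before use. Distinct fragments per window differed with a chi-square per degree of freedom of 45.5 between the WT libraries and 16.2 between the pol32 libraries, so no library was counted as a copy of another.

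The tests were run on simulated data, with noise drawn independently for each window or origin. All density windows shared the same dispersion, and no shift of whole libraries or regions was added as noise. The rates below therefore hold for the simulation and may differ in these libraries. With 200 of 2390 windows changed, edgeR recovered 25.4% of 1.2-fold, 98.5% of 1.5-fold and 100% of 2-fold changes and called 8 unchanged windows. With 200 of 2380 windows changed in strand ratio, limma recovered 0% at 0.25, 7.46% at 0.5 and 36.4% at 1 on the log2 scale. With 50 of 218 origins changed, limma recovered 23.1% of differences of 0.1 and 95.8% of differences of 0.2. A simulated repeat of 165 nt and a displacement of 9 nt were recovered as 165 and 9 nt.

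Tests and most alternatives were fixed before the data were examined, but for annotated genes, gene lists, annotated origins and the POL32 gene. Density windows, lists of windows, origins called from the data and the search for a lost interval replaced these afterwards, for want of a matching annotation. The alternatives were DESeq2 1.42.0, no filter on low counts, distinct fragments counted once, fragments of 100 to 220 nt alone, no windows within 20 kb of chromosome ends, thinning to the shallowest library, a replicate block, other window sizes, flanks, pseudocounts and smoothing, capped counts per position and leaving out each library. For named regions, the rule took windows past the threshold with both pol32 libraries on the same side of both WT libraries, the 10 largest each way for density, and the 5 largest each way past the threshold for strand share and origins. The comparison of chromosomes, that of adjoining ends, density windows of 1 and 10 kb and the leaving out of chromosomes 3, 11 and 15 were chosen after seeing the data.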

Results

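Okazaki fragments, the short pieces in which the lagging strand is made behind each replication fork, were sequenced from asynchronous cultures of Saccharomyces cerevisiae. The series holds 4 libraries, 2 from a wild-type strain (WT) and 2 from a strain without POL32 (pol32ko in the strain labels, pol32 here). POL32 encodes the non-essential subunit of DNA polymerase delta, the polymerase that extends most of the lagging strand. The study asked how the synthesis and maturation of these fragments are tied to chromatin. The 2 libraries of a group carry 1 strain name, and nothing in the labels says whether they came from separate cultures. The p-values below therefore measure at most the spread between these libraries. Any strain difference other than the deletion is also inseparable from the group.

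Depth and duplication differed widely between libraries. WT replicate 1 held 92755003 reads from 8185702 distinct fragments, or 11.3 reads per fragment. WT replicate 2 held 55096375 reads from 43324151 fragments, or 1.27 per fragment. In pol32 replicate 1, 48289128 reads came from 24040896 fragments (2.01 per fragment), and in pol32 replicate 2, 38470740 reads came from 11164558 fragments (3.45 per fragment). Both WT libraries thus held more reads than both pol32 libraries, but WT replicate 1 held the fewest distinct fragments of all. Duplication did not part the groups, since WT held the highest and the lowest number of reads per fragment. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, so that test could not reach 0.05 for any single value per library.

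The deleted gene was looked for first. Among 45496 windows of 250 nt that were covered in WT, 4 were nearly empty in pol32, and they were adjacent. They mark an interval on chromosome 10 from position 516401 to 517550 (1150 nt, build not given in the sources used here). POL32 (YJR043C, 1053 nt in the R64 gene table) lies on chromosome 10. The interval held 6049 and 4650 reads in WT replicates 1 and 2 against 41 and 35 reads in pol32. As reads per kb, scaled to 1000000 reads in a library (RPKM), these are 56.7 and 73.4 against 0.738 and 0.791, an 85.1-fold difference of the means (61.1-fold with distinct fragments counted once). No window was lost in WT relative to pol32. The interval was chosen by its loss, so no p is given, and the match to the gene rests on the chromosome and the length alone.

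A sequence of plasmid size was nearly absent from pol32, while one of mitochondrial size was not found to differ. The sequence numbered 18 in the files ends at position 6317, close to the size of the 2-micron plasmid, a multicopy circle carried by many yeast strains. It took 1.94% (95% Wilson interval 1.93 to 1.94) and 1.49% (1.49 to 1.49) of reads in WT replicates 1 and 2. In pol32 it took 0.0116% (0.0113 to 0.0119) and 0.0158% (0.0154 to 0.0162). The mean share was 125-fold lower in pol32, and between single libraries the fold ran from 94.5 to 167 (exact permutation p = 0.333, the smallest possible). With distinct fragments counted once the mean share was 50.2-fold lower, and the fold ran from 26.5 to 98.5. Reads per fragment on this sequence were 1.24 and 1.75 times those of the library in WT and 0.731 and 0.490 times in pol32. Counting fragments therefore lowers the fold. Read density on this sequence was 38.1 and 29.4 times the nuclear mean in WT, against 0.226 and 0.305 times in pol32. The sequence numbered 17, which ends at position 85778 and is close to mitochondrial DNA in size, took 1.40% ± 0.434 (SD, n = 2) of reads in WT and 1.47% ± 0.395 (SD, n = 2) in pol32 (exact permutation p = 0.667). The Wilson intervals count every read as independent. PCR copies are not independent molecules, so these intervals are narrower than the counting error of molecules and leave out the spread between libraries.

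Fragment length did not separate the groups. Nuclear reads had a median length of 163 and 137 nt in WT replicates 1 and 2 and of 153 and 158 nt in pol32 (exact permutation p = 1). The highest point of the length distribution lay at 136 and 124 nt in WT and at 117 and 137 nt in pol32 (exact permutation p = 1). A weaker shoulder followed at 313 and 320 nt in WT and 314 and 315 nt in pol32 (exact permutation p = 1), which put the 2 maxima 187 nt ± 13.4 (SD, n = 2) apart in WT and 188 nt ± 13.4 (SD, n = 2) in pol32. Reads of 250 to 400 nt were 0.167 ± 0.0202 (SD, n = 2) times as many as reads of 100 to 220 nt in WT and 0.154 ± 0.00426 (SD, n = 2) times in pol32 (exact permutation p = 0.667). WT replicate 2 stood apart, with 26.8% of its reads under 100 nt against 2.53%, 2.66% and 6.05% in the other libraries. The rule for the shoulder was set after the data were seen; with the highest point of the 250 to 400 nt range in its place, pol32 replicate 1 fell on the edge of the range and the difference in position, pol32 minus WT, went from -2 to 41 nt.

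**Figure D1:**
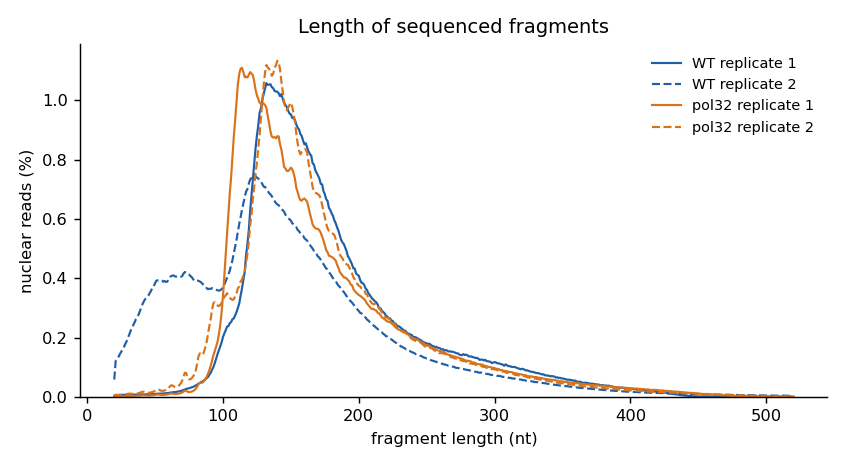
Share of nuclear reads (%) at each fragment length (nt), 1 line per library, WT in blue and pol32 in orange. Medians were 163 and 137 nt in WT and 153 and 158 nt in pol32, and WT replicate 2 held 26.8% of its reads under 100 nt.

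Whole chromosomes differed in fragment density. Chromosome 15 was lower in pol32 at 0.777-fold of WT (log2 difference -0.36, SE 0.0165, limma adjusted p = 0.000138), and chromosome 3 was lower at 0.735-fold (log2 difference -0.44, SE 0.0316, limma adjusted p = 0.000519). Chromosome 11 was higher at 1.16-fold (log2 difference 0.21, SE 0.0196, limma adjusted p = 0.00118). On chromosome 3, densities were 80.2 and 81.9 RPKM in WT and 57.9 and 61.3 in pol32. On chromosome 15 they were 85.3 and 84.9 in WT and 65.3 and 66.9 in pol32, and on chromosome 11, 91.3 and 88.4 in WT and 104 and 103 in pol32. The shift ran along each chromosome, with 62 of 62 windows of 5 kb lower on chromosome 3, 216 of 217 lower on chromosome 15 and 125 of 133 higher on chromosome 11. Chromosomes 4 (1.07-fold) and 5 (1.04-fold) also passed the test, with limma adjusted p of 0.00825 and 0.0289, but neither passed it on the Watson strand alone or the Crick strand alone. Chromosome 5 also lost its call with a replicate block (limma adjusted p = 0.0660), without WT replicate 1 (0.348) and without WT replicate 2 (0.180), and chromosome 4 without WT replicate 2 (0.0721). This comparison was added after the windows had been seen.

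**Figure D2:**
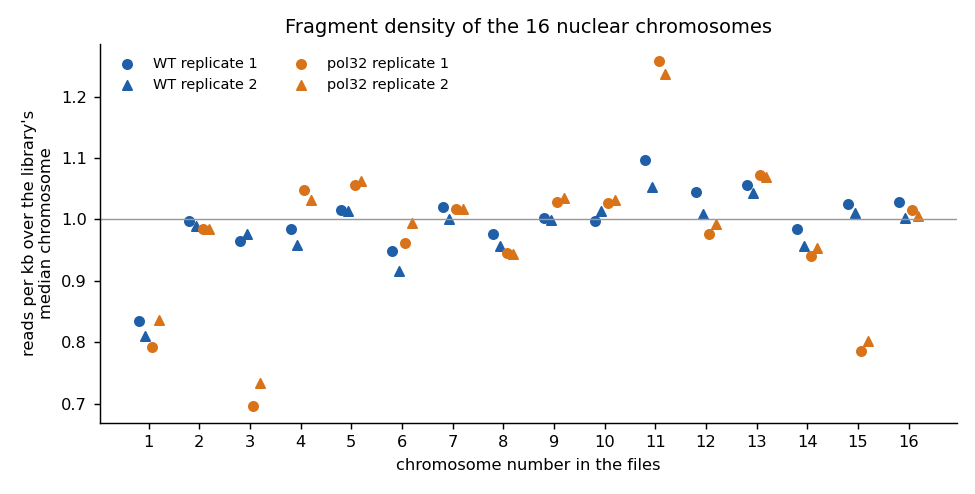
Reads per kb on each of the 16 nuclear chromosomes, divided by the median chromosome of the same library; each point is 1 library, and the vertical axis does not start at 0. Chromosomes 3 and 15 lay at 0.697 to 0.802 in pol32 and at 0.964 to 1.03 in WT, and chromosome 11 lay at 1.24 and 1.26 in pol32 and 1.05 and 1.10 in WT.

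In 5 kb windows, edgeR's quasi-likelihood test called 278 of 2390, with 62 higher and 216 lower in pol32. Chromosome 15 held 153 of the lower windows and chromosome 3 held 36, and chromosome 11 held 35 of the higher windows and chromosome 4 held 19. Largest among the increases were chr11_510001 (position 510001 to 515000, log2 0.43, SE 0.0690, edgeR adjusted p = 0.0185) and chr11_495001 (position 495001 to 500000, log2 0.42, SE 0.0826, adjusted p = 0.0236). Of the 10 largest increases, 8 lay on chromosome 11 and 2 on chromosome 4 (chr4_1160001 and chr4_600001, log2 0.39 and 0.37). Largest among the decreases were chr3_310001 (log2 -0.96, SE 0.125, adjusted p = 0.0185) and chr3_305001 (log2 -0.90, SE 0.122, adjusted p = 0.0185), next to the right end of chromosome 3. The other large decreases were 3 more windows of chromosome 3, 3 of chromosome 15 (chr15_1, log2 -0.85, chr15_5001 and chr15_1070001) and 2 at the left end of chromosome 7 (chr7_1 and chr7_5001, log2 -0.79 and -0.66). Without chromosomes 3, 11 and 15, edgeR called 0 of 1978 windows, with 331 at an unadjusted p under 0.05. The named windows of chromosomes 4 and 7 lost their calls there but kept their direction, so a lack of calls does not show a lack of differences. The count also moved with single libraries, to 581 without WT replicate 1, 679 without WT replicate 2, 0 (291 unadjusted) without pol32 replicate 1 and 14 without pol32 replicate 2, and 1 kb windows gave 0 calls (2040 of 11765 unadjusted) and DESeq2 789.

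**Figure D3:**
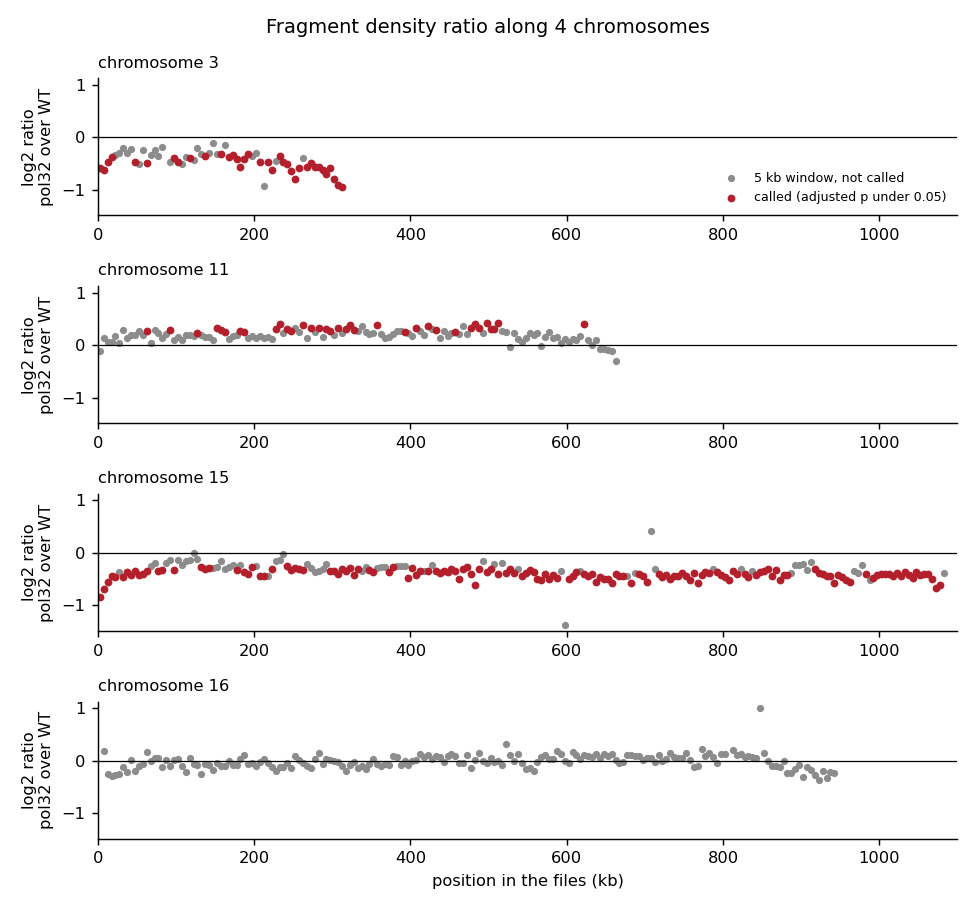
Log2 ratio of fragment density, pol32 over WT, in 5 kb windows along chromosomes 3, 11, 15 and 16, by position in the files (kb); red points passed edgeR's test at an adjusted p under 0.05. Windows lay below 0 along chromosomes 3 and 15 (62 of 62 and 216 of 217) and above 0 along most of chromosome 11 (125 of 133), while chromosome 16 had no called window.

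Windows near chromosome ends were lower in pol32 as a group. The 123 windows within 20 kb of an end had a median log2 ratio of -0.26, against 0.01 elsewhere, and 27 of them were called lower and 0 higher (27 lower when adjusted over the list alone). The list stood apart in limma's camera test (adjusted p = 1.19e-15 with a preset correlation), and adjusted p = 0.0138 with an estimated correlation. Outside chromosomes 3, 11 and 15 the median was -0.24. The 435 windows within 5 kb of an origin called from these data had a median of 0.02, with 13 called higher and 39 lower (14 higher and 39 lower when adjusted over the list alone; camera adjusted p = 0.488, and adjusted p = 0.586 with an estimated correlation).

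Replication origins stood out as switches in the strand of the fragments. A fork moving left makes its lagging strand as Watson-strand fragments and a fork moving right as Crick-strand fragments, so an origin shows as a fall in the Watson share from left to right. Across the 4 libraries 218 such origins were called, with a median spacing of 50.5 kb. In the bin centred 1750 nt to the left of them, 83.0% and 77.5% of reads lay on the Watson strand in WT replicates 1 and 2 and 77.4% and 75.1% in pol32. At 1750 nt to the right the shares were 19.3% and 23.0% in WT and 24.2% and 26.6% in pol32. Closer to the origins the groups overlapped, as WT replicate 2 lay nearer to 50% than both pol32 libraries. At 250 nt to the left the shares were 72.6% and 63.8% in WT and 70.2% and 69.5% in pol32, and at 250 nt to the right 28.5% and 35.8% in WT and 30.4% and 31.2% in pol32. Fork direction was largely shared by the strains, since 94.7% of 2380 windows had the same majority strand and the log2 strand ratios correlated at r = 0.979 across windows, which are not independent replicates.

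**Figure D4:**
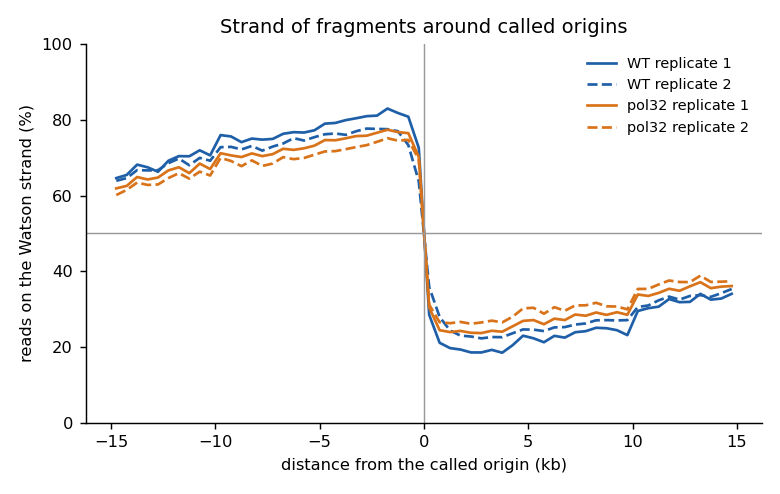
Percentage of reads on the Watson strand by distance (kb) from the 218 called origins, in 500 nt bins, 1 line per library. At 1750 nt to the right of the origins the share was 19.3% and 23.0% in WT and 24.2% and 26.6% in pol32.

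In most windows the strand bias of fragments was weaker in pol32. The Watson share lay on average 25.8 and 24.0 percentage points away from 50% in WT replicates 1 and 2, and 23.3 and 21.1 points in pol32. The group means were 2.67 points apart (exact permutation p = 0.333, the smallest possible), while replicates differed by 1.79 points in WT and 2.25 in pol32. The share was closer to 50% in pol32 in 1817 of 2380 windows. With limma, 73 windows were called, 33 with a higher and 40 with a lower Watson share in pol32, and 61 of the 73 were closer to 50% in pol32. On chromosome 9, the Watson share of chr9_390001 fell from 80.8% in WT to 55.9% in pol32 (log2 ratio difference -1.74, SE 0.282, limma adjusted p = 0.000838). The neighbouring chr13_885001 and chr13_890001 fell from 68.3% to 42.5% and from 76.9% to 51.4% (log2 ratio differences -1.54 and -1.66, limma adjusted p = 0.00137 and 0.000991). In the other direction, the neighbours chr5_60001 and chr5_65001 rose from 24.7% to 46.8% and from 33.0% to 59.0% (1.44 and 1.55, limma adjusted p = 0.00372 and 0.00137). Also named by the rule were chr8_540001, chr8_65001 and chr3_50001, which rose by 1.45, 1.33 and 1.31, chr9_395001, which fell by 1.55, and chr4_985001, which fell by 1.69 but held only 4.46, 2.27, 6.01 and 8.27 reads per 1000000. Leaving out pol32 replicate 1 or 2 gave 0 calls with limma (195 and 68 unadjusted), leaving out WT replicate 1 or 2 gave 431 and 818, and counting distinct fragments once gave 132 and 1 kb windows 0 (1167 unadjusted).

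Origins were less efficient in both pol32 libraries than in both WT libraries. Efficiency, the Watson share in the 10 kb to the left of an origin minus that in the 10 kb to the right, had a median of 0.584 and 0.522 in WT replicates 1 and 2 and of 0.491 and 0.436 in pol32. The mean over origins differed by 0.0789 between the groups (exact permutation p = 0.333, the smallest possible) and by 0.0688 and 0.0470 between replicates of WT and pol32, and the nearest WT and pol32 libraries were 0.0210 apart. Efficiency was lower in pol32 at 205 of 218 origins, and at 122 both pol32 libraries lay below both WT libraries. With limma, 24 origins were called lower and 0 higher in pol32 (65 of 218 at an unadjusted p under 0.05). Each test included the shift in overall level (median difference -0.0722), so a call does not show a change particular to that origin. At the origin ori13_897901 on chromosome 13, position 897901, efficiency was 0.612 ± 0.0362 (SD, n = 2) in WT and 0.322 ± 0.0530 (SD, n = 2) in pol32 (limma adjusted p = 1.78e-05). At ori14_738601 it was 0.477 ± 0.0407 (SD, n = 2) in WT and 0.218 ± 0.0272 (SD, n = 2) in pol32 (limma adjusted p = 0.000167). At ori5_59201, ori1_70401 and ori7_17701 it fell by 0.248, 0.244 and 0.230. Limma gave every origin the same SE (0.0532), pooled over all origins as if they varied independently. Its p-values for origins therefore do not rest on the SD at each origin. The strains' mean efficiencies correlated at r = 0.928 across origins. The count was 28 without WT replicate 1, 102 without WT replicate 2, 5 without pol32 replicate 1 and 0 (13 unadjusted) without pol32 replicate 2, and 9 with 5 kb flanks.

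**Figure D5:**
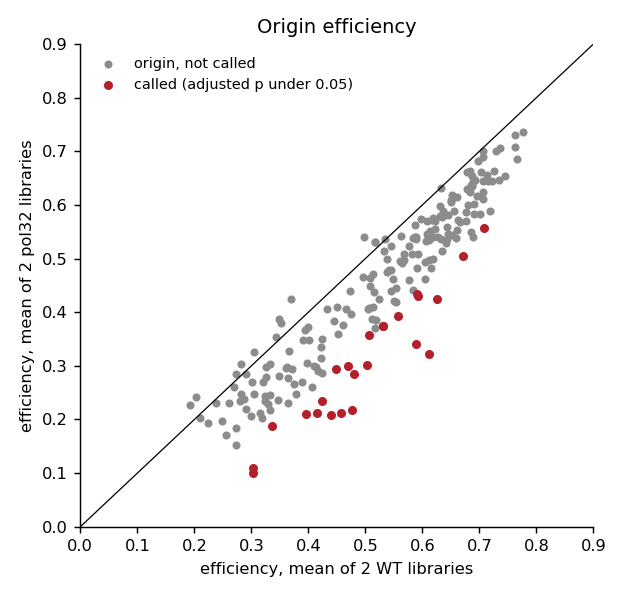
Efficiency of the 218 called origins, mean of the 2 pol32 libraries against mean of the 2 WT libraries, with the line of equality; red points passed limma's test at an adjusted p under 0.05. Efficiency was lower in pol32 at 205 origins, and the 24 called origins all lay below the line.

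No displacement of fragment ends was detected between WT and pol32. The cross-correlation of 5′ ends was highest at a lag of 0 nt for all 4 pairs of a WT and a pol32 library and for both pairs within a group, on every chromosome, and the same held for 3′ ends. Preferred single positions that all libraries share would hold this lag at 0, so a small displacement of a broader distribution was not excluded. Within libraries, the autocorrelation of 5′ ends between 120 and 220 nt was highest at 129 and 120 nt in WT and at 120 and 120 nt in pol32, where 120 nt is the edge of the range (exact permutation p = 1). For 3′ ends the highest lag was 129 and 130 nt in WT and 120 and 132 nt in pol32 (exact permutation p = 1). The heights were low, 0.0386 ± 0.0173 (SD, n = 2) in WT and 0.0384 ± 0.0145 (SD, n = 2) in pol32 for 5′ ends and 0.00854 ± 0.00818 (SD, n = 2) and 0.00797 ± 0.00421 (SD, n = 2) for 3′ ends (exact permutation p = 1 for each).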

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

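Alternatives chosen after seeing the data were the leaving out of chromosomes 3, 11 and 15, 1 and 10 kb density windows, nuclear totals, the crossed pairing and all settings of the chromosome and adjoining-end comparisons. The other shoulder rule was the first one set, and the rule used in its place was chosen after seeing the data. Under other settings, chromosomes 3, 11 and 15 kept direction and call in 18 of 18 values. Named density windows did in 150 of 156, strand windows in 29 of 29 and origins in 20 of 20. With 1 library left out, many windows and some origins lost calls. Direction could not turn there, as both pol32 libraries lay on one side of both WT libraries. The list of windows near chromosome ends stayed past the threshold in all 6 of its alternatives.

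Counts of calls depended on single libraries. With 1 left out they ran from 0 to 679 density windows, 0 to 818 strand windows, 0 to 102 origins and 3 to 8 chromosomes, against 278, 73, 24 and 5. Leaving out a pol32 library leaves the spread to the WT pair, which differed more in density than the pol32 pair (SD of log2 ratios 0.192 against 0.157), and the lone library is assumed to vary like it. DESeq2 called 789 density windows (348 higher and 441 lower, against 62 and 216 with edgeR), which held 277 of the 278. Without chromosomes 3, 11 and 15 edgeR called 0 (331 unadjusted), and with 1 kb windows 0 (2040 unadjusted). Distinct fragments gave 132 strand windows and 1 kb windows 0 (limma, 1167 unadjusted). Flanks of 5 kb gave 9 origins, and the Watson strand alone 3 chromosomes. The cause of these changes was not tested.

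The labels do not pair the libraries. Replicate differences of WT and pol32 correlated at 0.242 for density, 0.124 for strand share and -0.320 for origins. The replicate block gave 432 density windows, 145 strand windows and 78 origins, and moved 5 chromosomes to 6. The crossed pairing gave 5 origins.

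Lengths and lags that overlapped between the groups (pol32 minus WT) came apart under some settings of all 4 libraries (exact permutation p = 0.333, the smallest possible). For the 3′ end lag these were distinct fragments (132 and 129 nt in WT, 120 and 120 nt in pol32) and capped counts (126 and 129 against 120 and 123 nt), and for the shoulder 21 nt smoothing (314 and 322 against 310 and 313 nt). With 1 library left out they came apart for median length and shoulder (without WT replicate 1), length ratio and 5′ end lag (without WT replicate 2) and 3′ end lag (without either pol32 library, in opposite directions). Most values also changed sign. With 1 library left out, they ran from -7.5 to 18.5 nt for median length, -13 to 7 nt for the first peak, -5.5 to 1.5 nt for the shoulder, -8.5 to 10.5 nt for the spacing, -0.0275 to 0.00109 for the length ratio and -0.240 to 0.374 percentage points for chromosome 17. The ranges were -9.5 to 2.5 nt for the 3′ end lag, -0.0124 to 0.0120 for the 5′ height and -0.00635 to 0.00522 for the 3′ height. Smoothing over 21 nt gave a difference in spacing of -4 nt, the other shoulder rule a shift of the shoulder of 41 nt, and distinct fragments heights of 0.00627 (5′) and 0.000373 (3′). Depth limits the remaining reads in the lost interval, 41 and 35. Comparisons of genes, gene lists, motif sites, tRNA genes, start codons, Ty elements and ribosomal DNA, with their other settings, were not run for want of an annotation of the build.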

Other observations

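The comparison of adjoining ends and the tests below of duplication, plasmid retention, carry-over, even mixing and the spread between libraries were chosen after the values they rest on had been seen, and that of origin firing before. Fragment ends of the same strand adjoined each other. In each of the 4 libraries the offset from a 3′ end to a 5′ end with the most pairs was 1 nt, the next nucleotide, as at a nick. Pairs at this offset were 1.45 and 1.36 times the background in WT replicates 1 and 2 and 1.28 and 1.28 times in pol32. Both WT libraries lay above both pol32 libraries (exact permutation p = 0.333, the smallest possible).

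The first pattern is the lower density of chromosomes 3 and 15 and the higher density of chromosome 11 in pol32. Unequal duplication or depth is argued against, since counting distinct fragments once kept at least 96.2% of each log2 difference and all 3 calls. Altered firing of some origins stays open. Windows within 5 kb of origins and windows farther away differed by at most 22.5% of a chromosome's own shift, but changed firing would reach over the distance between origins (median 50.5 kb), so the bound set beforehand was wrong and this contrast decides nothing. A changed number of copies of these chromosomes in the pol32 strain stays open, as does an effect of the deletion. Of 2 tests of copy number that were tried and dropped, the share of windows on a chromosome's side of 0 only restated the pattern, and the spread of windows within a chromosome had its bound chosen after the values were known.

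The second pattern is the small number of reads left in pol32 on the plasmid-sized sequence and in the lost interval. Plasmid kept in a small part of the cells stays open. The remaining plasmid fragments had 1.47 and 1.69 reads each in pol32 replicates 1 and 2, while nuclear windows of 1 kb that were no denser (183 and 141 windows) had medians of 1.96 and 3.37, and 0% of them lay lower. Sequences other than the nuclear chromosomes need not follow the duplication of those chromosomes, however. Relative to its library, the plasmid stood at 0.731 and 0.490 in pol32 and at 1.24 and 1.75 in WT. The mitochondrial-sized sequence stood at 0.980 and 0.858 in pol32, above the plasmid, and at 0.725 and 1.12 in WT. The plasmid in pol32 had to lie below every ratio of that sequence, a bound added after the values were known. The 0.731 of pol32 replicate 1 did not lie below the 0.725 of WT replicate 1. Fragments in the lost interval, few as they were, had 1.71 and 2.06 reads each. Carry-over of WT fragments stays open. It requires 1 share of the WT level for both regions, and these matched, within the Poisson interval of the interval's 24 and 17 fragments, for 3 of 6 pairs of source and unit. With fragments counted, WT replicate 1 and the mean of WT matched in both pol32 libraries. With reads counted, WT replicate 2 alone did, so no source matched in both units. In WT, reads per fragment relative to the library were 0.981 and 0.965 in the interval, against 1.24 and 1.75 on the plasmid. Counting fragments thus lowers the WT level of the plasmid relative to the interval. With the mean of WT, pol32 replicate 1 held 1.30% (fragments) and 1.14% (reads) of the WT level in the interval against 1.32% and 0.678% on the plasmid.

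The third pattern is the lower strand bias and origin efficiency in pol32. Strand-neutral fragments mixed evenly into the pol32 libraries would scale all origins alike only where the density of other fragments is equal. Density in pol32 was not even, with chromosome 3 at 0.735-fold of WT and a median log2 ratio of -0.26 near chromosome ends. The ratio of pol32 to WT efficiency was 0.775 at the 109 less efficient origins and 0.895 at the 109 more efficient ones. The difference was -0.120 (95% bootstrap interval over origins -0.150 to -0.0897), against -0.0205 between the WT libraries and -0.00853 between the pol32 libraries. This difference argues against even mixing where density is even. Across origins, pol32 efficiency on WT efficiency had a slope of 0.971 and an intercept of -0.0636, while even scaling would leave no intercept. Density was not compared between the less and the more efficient origins, so even mixing with uneven density stays open. The spread between libraries of 1 group cannot be told apart from a strain effect on the overall level. The group means lay 2.67 percentage points apart in mean distance from 50%, but the lowest WT and the highest pol32 library only 0.649, while replicates differed by 1.79 and 2.25 points. Mean origin efficiency behaved alike, but it is computed from the strands of the same reads and is no separate evidence. It differed by 0.0789 between the means, 0.0210 between the nearest libraries, and 0.0688 and 0.0470 between replicates. The 2 libraries per group are too few to decide. An effect of the deletion stays open, as untested.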
